A study of Mus musculus with 8 samples.

How the data were processed

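RNA was measured by sequencing of poly-A enriched, stranded libraries made from total RNA of the whole mouse aortic tree, per the labels' protocols. The 8 libraries fall into 4 groups of 2: wild-type (WT) and smooth muscle specific Tet2 knockout mice, each given vehicle or VitD. Groups and replicate numbers were taken from the sample titles. The labels name no dose, duration, age or number of mice per library. Nothing says whether the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

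The deposited values are raw read counts per gene symbol. Trimmomatic 0.39, STAR 2.7.8a, featureCounts 2.0.2 and the build mm10 are named in the submitters' processing notes. The annotation release, strand setting and treatment of reads that map to several places are not given in the sources used here. Reads of near-identical genes, such as Hspa1a and Hspa1b, and of members of the Serpina3, Mup, Saa and Stfa families, could therefore be split or lost, and values of these genes are uncertain. Coordinates come from GENCODE M21 (mm10), matched by symbol, where 46378 of 48587 symbols (95.5%) matched exactly 1 gene.

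Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM normalisation and the filterByExpr filter, which kept 16194 genes. Of the 48587 symbols, 20586 had no count in any library. A quasi-likelihood model with 1 mean per group was fitted to all 8 libraries (4 residual degrees of freedom) without covariates, and 5 contrasts were tested: VitD against vehicle in each genotype, genotype under each treatment, and their interaction. P-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. Standard errors (SE) were derived from the fold change and the F statistic. CPM is the TMM-normalised count scaled to library size, given as mean ± SD over 2 libraries. For a gene with no count in a group, the fold is a bound against a floor of 3 counts over the group. Such floors cover counting error only.

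Before the data were examined, 37 gene lists were fixed, covering pathways, other cell types of a dissected aorta, handling, time of day and sex. Some genes stand in several lists, such as Spp1 (osteochondrogenic, modulated smooth muscle), Vcam1 (modulated smooth muscle, inflammation) and Lcn2 (inflammation, neutrophils). Lists that share members are therefore not independent of each other. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 37 lists. No list was called in any contrast when the correlation was estimated from the data. At an unadjusted p under 0.05 the estimated correlation left 5, 8, 2, 1 and 2 lists in the order of the contrasts above. Calls by the fry test, which asks whether the genes of a list move on balance one way, numbered 12, 7, 0, 0 and 0, with 17, 10, 1, 1 and 2 at an unadjusted p under 0.05.

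The genes named were set by a rule fixed before the data were examined. It takes 6 genes always (Tet2, Cyp24a1, Runx2, Acta2, Myh11, Spp1) as values. It adds the 8 largest rises and 8 largest falls (5 each for the interaction) among called genes with a mean of at least 1 CPM in the higher group and no overlap between groups, leaving out predicted genes. It also takes up to 4 called members of each described list, or up to 2 members with the smallest p where none was called. Which lists are described, and how many of their members, was chosen after the values were seen. Other genes named outside the rule are said to be so.

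Alternatives planned before the data were examined were DESeq2 size factors, upper quartile normalisation, DESeq2 1.42.0, limma voom with quality weights, no filter, a filter of 1 CPM in 2 libraries, the replicate number as a block, the library number range as a covariate, a fit of only the groups compared, an estimated correlation, and leaving out each library. DESeq2 was run on every gene with a count, without filterByExpr, so its calls differ from those of edgeR in filter as well as tool. Removal of trends with transcript length, or length and GC content, and fry were added after seeing the data. So was a linear model of the contractile list's median deviation per library over the 8 libraries, with 95% intervals from the t distribution. The library names carry numbers in 2 ranges, 3418 to 3423 (5 libraries) and 6828 to 6831 (3 libraries), which the labels do not call batches.

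The procedure was tested on simulated counts of 16194 genes for VitD against vehicle in WT. It recovered 17% of 100 genes changed by a log2 of 1 and 79% of 100 changed by a log2 of 2, with 4 false calls. Far fewer genes were changed there than the 3251 called in the real data. The adjustment of p-values depends on that share, so these percentages do not give the recovery in the real contrast. The simulated list that was moved was called, and 0 of the unmoved lists were called by camera. Simulated genes were drawn independently of each other, whereas the estimated correlation was, for example, 0.792 among proliferation genes in WT. The simulation therefore does not test the camera calls under such correlation. The replicates of each group were compared by chi-square before averaging. The ratio to its degrees of freedom lay between 26.1 and 105, so replicates of a group were not copies of one another. Libraries of different groups were not compared in this way. A sex covariate was not used because all 8 libraries carried Y-linked counts (Ddx3y 2301 to 3218 counts) and at most 23 Xist counts.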

Results

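Expression was profiled in the whole aortic tree of mice given vehicle or vitamin D (VitD in the labels), either WT or labelled as carrying a Tet2 knockout in vascular smooth muscle cells. Vitamin D overload is a known way to provoke calcification of the arterial media, and TET2 is an enzyme that oxidises methylated cytosine in DNA. The series asks how Tet2 in smooth muscle bears on osteogenic change and medial calcification of the aorta. Each group held 2 libraries, with 15679274 to 22332149 counts per library.

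Tet2 (chromosome 3, 133463679 to 133545139, minus strand, mm10) was not lower in the libraries labelled Tet2 knockout. It stood at 42.0 and 35.2 CPM in the vehicle libraries labelled Tet2 knockout, against 35.8 and 32.2 CPM in WT (log2 fold change 0.18, SE 0.21, adjusted p = 1). Under VitD it stood at 26.6 and 37.6 CPM in the libraries labelled Tet2 knockout, against 18.3 and 20 CPM in WT (log2 0.74, SE 0.212, adjusted p = 0.457). Without Tet2KO_VitD 1 the latter was 0.95 with an adjusted p of 0.0409, and without Tet2KO_VitD 2 it was 0.47 with an adjusted p of 0.651. The genotype label was thus not borne out by the gene-level count. The deleted part of Tet2 is not given in the sources used here, and the aorta holds other cells, so these counts check the label only in part. Every genotype direction below rests on that label.

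**Figure D1:**
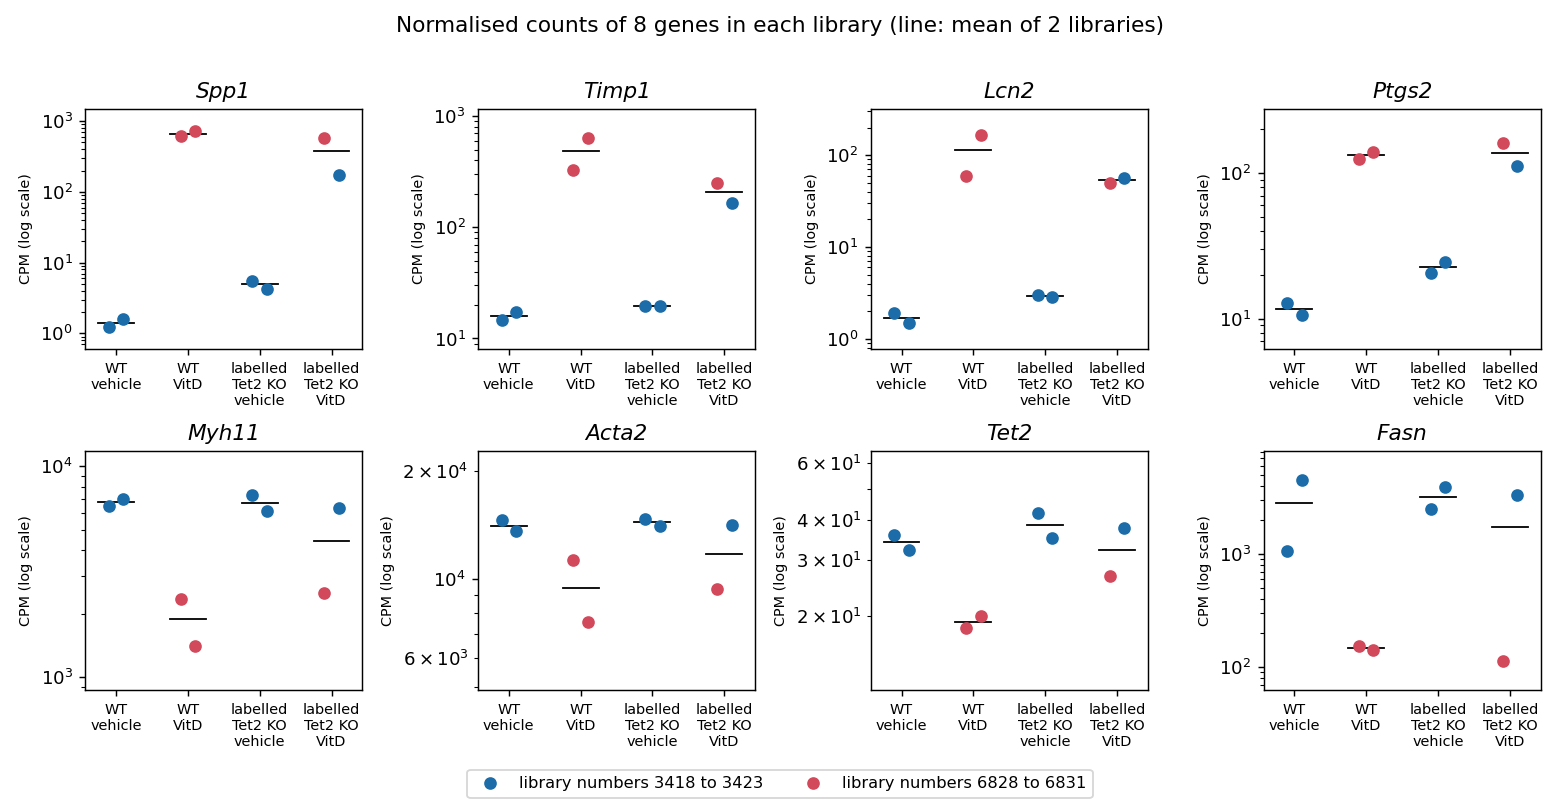
Normalised counts (CPM, log axis) of 8 genes in each of the 8 libraries, coloured by library number range, with lines at the mean of the 2 libraries of a group. Tet2 lies at 18.3 to 20 CPM in WT under VitD and at 26.6 CPM or more in the other libraries, and Fasn is low in the 3 libraries of the higher number range.

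VitD against vehicle in WT asks what the treatment does to the aorta of control mice. Spp1 (chromosome 5, 104435118 to 104441050), which encodes the mineral-binding matrix protein osteopontin, rose from 1.42 ± 0.249 to 664 ± 75.5 CPM (SD, n = 2), a log2 fold change of 8.86 (SE 0.657, adjusted p = 0.000993). Timp1, a metalloproteinase inhibitor, rose 30.2-fold to 483 ± 221 CPM (log2 4.92, SE 0.377, adjusted p = 0.00109). Myh11 (chromosome 16, 14194535 to 14291372), the smooth muscle myosin heavy chain, fell by 1.84 on the log2 scale (SE 0.439, adjusted p = 0.0246), from 6726 ± 349 to 1877 ± 666 CPM. Tet2 itself fell by 0.83 on the log2 scale in WT (SE 0.213, adjusted p = 0.0305). With the library number range as a covariate Myh11 stood at -0.51 (adjusted p = 0.74) and Tet2 at -0.33 (adjusted p = 0.746). Both calls ended without WT_vehicle 1 (adjusted p = 0.097 and 0.131), WT_vehicle 2 (0.0838 and 0.075), WT_VitD 1 (0.055 and 0.162) or WT_VitD 2 (0.18 and 0.174), and that of Tet2 also without Tet2KO_vehicle 1 (0.052) or Tet2KO_vehicle 2 (0.0516). Acta2, smooth muscle actin, had a log2 fold change of -0.58 (SE 0.311, adjusted p = 0.202), which was 0.018 with the number range as a covariate, and Runx2, the osteoblast transcription factor, 0.66 (SE 0.419, adjusted p = 0.273). Cyp24a1, the vitamin D degrading enzyme, had 0 or 1 counts in every library and was not tested.

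By edgeR, 3251 genes changed in WT, 1718 higher and 1533 lower under VitD. Among the largest rises were Chil3, a chitinase-like protein of macrophages, at 7.77 (SE 0.884), and genes with no count under vehicle. Of these, Hmga2, an architectural chromatin protein, was at least 75.1-fold higher, the neutrophil chemokine Cxcl3 at least 23.7-fold, Fgf23, a phosphate-regulating hormone, at least 17-fold, the neutrophil antigen Cd177 at least 15.4-fold, Stfa2l1 at least 15.1-fold and Xkr5 at least 12.5-fold. Genes absent under VitD included Dntt, a thymocyte polymerase, at least 66.8-fold lower, Pzp at least 20-fold, Fer1l6 at least 17.7-fold, Mir6365 at least 11.5-fold and Adamts16 at least 11-fold lower. Crip3 (log2 -5.40), the urinary protein gene Mup3 (log2 -5.37) and the fatty acid binding Fabp1 (log2 -5.32) also fell. Dntt lay at 12 CPM in WT_vehicle 1 and 0.228 CPM in WT_vehicle 2, so its level rests on a single library. The count was 58 (56 higher) with the library number range as a covariate, under which 8 of the 66 called genes named for this comparison kept their call. Of these 66 genes, 19 and 23 kept it without WT_vehicle 1 and 2, 36 and 14 without WT_VitD 1 and 2, and 53 without Tet2KO_vehicle 1 or 2. It was 226 without WT_vehicle 1, 594 without WT_vehicle 2, 1996 and 2019 without Tet2KO_vehicle 1 and 2, 1007 and 140 without WT_VitD 1 and 2, and 4946 and 4927 without Tet2KO_VitD 1 and 2.

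Contractile smooth muscle genes fell as a list in WT (camera adjusted p = 0.00187, adjusted p = 0.581 with an estimated correlation), with 5 of 20 members called lower and none higher, also 5 when adjusted over the list alone, and a median log2 of -0.572 over all 20. The difference of the list's median per library was -0.613 (95% interval -1.26 to 0.0383). Besides Myh11, the actin-binding Synpo2 (log2 -1.74, SE 0.348), the integrin Itga8 (log2 -1.53, SE 0.337) and smoothelin, Smtn (log2 -1.38, SE 0.409), fell. Calcification inhibitors rose as a list (adjusted p = 0.00498, adjusted p = 0.226 with an estimated correlation), with 4 of 9 members called higher, 4 adjusted over the list alone. Mgp, matrix Gla protein, rose from 1757 ± 347 to 6265 ± 1695 CPM, and osteoprotegerin, Tnfrsf11b, rose 3.45-fold. Gas6, a vitamin K dependent ligand, rose 3.12-fold and fetuin, Ahsg, 3.40-fold, though with the number range as a covariate the log2 of Ahsg was -0.23. Of 17 osteochondrogenic genes, 6 were called higher and 2 lower, 6 and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0523, fry adjusted p = 0.0382). RANK ligand, Tnfsf11, had a log2 of 4.75 (SE 1.18), Alpl, the alkaline phosphatase that frees phosphate for mineral, 2.89 (SE 0.448), and the collagen Col11a1 2.83 (SE 0.702). With the number range as a covariate the contractile smooth muscle list had an adjusted p of 0.158, calcification inhibitors 0.0515 and the osteochondrogenic list 1.21e-05. The osteochondrogenic list was also called without Tet2KO_vehicle 1 (adjusted p = 0.0381), WT_VitD 1 (0.0366), WT_VitD 2 (0.0163), Tet2KO_VitD 1 (0.0147) or Tet2KO_VitD 2 (0.0146).

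The vitamin D response list rose in WT (adjusted p = 0.0483, adjusted p = 0.443 with an estimated correlation), with 4 of 7 tested members called higher, and 4 higher and 1 lower adjusted over the list alone. It was not called without WT_vehicle 1 (adjusted p = 0.0517), WT_vehicle 2 (0.105), Tet2KO_VitD 1 (0.0673) or Tet2KO_VitD 2 (0.0616). Its called members were Fgf23, Tnfsf11, the vitamin D receptor Vdr, up 5.87-fold, and Igfbp3, up 4.20-fold. Calcium and phosphate handling genes fell as a list (adjusted p = 0.00799, adjusted p = 0.411 with an estimated correlation), with 4 of 14 called lower and 5 adjusted over the list alone. With the number range as a covariate the calcium and phosphate handling list had an adjusted p of 0.0743. The L-type calcium channel Cacna1c (log2 -1.86) and the IP3 receptor Itpr1 (log2 -1.58) fell. Of 12 genes of the TET and DNA methylation machinery, 3 were called higher and 2 lower, 3 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.769). The maintenance factor Uhrf1 rose 4.01-fold, Gadd45a 3.01-fold and Idh1 1.74-fold.

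Genes of modulated smooth muscle, inflammation and macrophages each rose as a list in WT. Among modulated smooth muscle genes 13 of 16 were called higher, 13 adjusted over the list alone (camera adjusted p = 4.81e-20, adjusted p = 0.195 with an estimated correlation), including Igfbp2 (log2 3.61, SE 0.388) and S100a4 (log2 3.36, SE 0.819). The inflammation list had 18 of 20 called higher, 19 adjusted over the list alone (adjusted p = 3.07e-25, adjusted p = 0.186 with an estimated correlation). The cytokine Il6 rose by 7.16 (SE 0.91), the acute phase gene Saa3 by 6.28 (SE 0.69), lipocalin, Lcn2, by 6.05 (SE 0.511) and the chemokine Cxcl5 by 5.32 (SE 0.799) on the log2 scale. Macrophage genes rose in 14 of 15 cases, 14 adjusted over the list alone (adjusted p = 3.95e-20, adjusted p = 0.195 with an estimated correlation), with Trem2 up 13.7-fold and the protease Ctss up 7.29-fold. Neutrophil genes had 7 of 11 called higher, 8 adjusted over the list alone (adjusted p = 3.57e-08, adjusted p = 0.389 with an estimated correlation), including the decoy receptor Il1r2, up 56.9-fold. Interferon response genes had 14 of 16 called higher, 14 adjusted over the list alone (adjusted p = 4.66e-14, adjusted p = 0.195 with an estimated correlation), among them Ifi44, up 9.47-fold, and Zbp1, up 6.33-fold.

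Proliferation genes had 16 of 18 members called higher in WT, 18 adjusted over the list alone (adjusted p = 5.6e-14, adjusted p = 0.411 with an estimated correlation), with the mitotic kinases Cdk1 up 9.78-fold and Plk1 up 8.30-fold. Metalloproteinases and inhibitors had 7 called higher and 1 lower of 16, 10 and 1 adjusted over the list alone (adjusted p = 1.63e-06, adjusted p = 0.344 with an estimated correlation), and the collagenase Mmp13 rose 16.6-fold. Oxidative stress genes had 9 of 14 called higher, 9 adjusted over the list alone (adjusted p = 2e-05, adjusted p = 0.411 with an estimated correlation), with the metallothioneins Mt2 up 25.4-fold and Mt1 up 8.88-fold. Circadian clock genes fell as a list, with 4 of 15 called lower, and 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.00501, adjusted p = 0.443 with an estimated correlation). The clock genes Nr1d1 (log2 -2.02) and Per2 (log2 -1.81) fell. The heat shock genes Hspa1b (log2 -2.74) and Hspa1a (log2 -2.66) fell, while their list of 14 had 2 called higher and 4 lower, 2 and 4 adjusted over the list alone (adjusted p = 0.712). Wnt pathway genes went both ways, 2 higher and 2 lower of 13, 3 and 4 adjusted over the list alone (adjusted p = 0.443), with Dkk2 up 5.04-fold and the inhibitor Wif1 at a log2 of -2.01. Among 18 glycolysis and hypoxia genes 3 were called higher and 3 lower, 3 and 3 adjusted over the list alone (adjusted p = 0.888), and Car9 (log2 -2.74) and Pfkp (log2 -1.11) fell.

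Lists of tissue outside the vessel wall were measured too. Skeletal muscle genes had 8 of 11 called higher in WT under VitD, and 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.000524, adjusted p = 0.443 with an estimated correlation), and Atp2a1 stood at 50.3 ± 60.8 CPM and Myh4 at 52.3 ± 59.7 CPM against 1.85 ± 0.114 and 2.38 ± 0.736 CPM under vehicle. Mesothelial and epithelial genes had 4 of 9 called higher, 9 adjusted over the list alone (adjusted p = 0.00107, adjusted p = 0.443 with an estimated correlation), including Msln (log2 2.99) and Wt1 (log2 1.97). T cell and thymocyte genes had 2 of 12 called lower, 2 adjusted over the list alone (adjusted p = 0.0731), and Rag1, the thymocyte recombinase, stood at 37.4 CPM in WT_vehicle 1 but 0.057 CPM in WT_vehicle 2, with a log2 fold change of 0.64 without WT_vehicle 1. The list of T cells and thymocytes was called lower without WT_vehicle 2 (adjusted p = 3.75e-10) and with the number range as a covariate (adjusted p = 0.00189). Fatty acid synthase, Fasn, fell by 4.24 on the log2 scale (SE 1.28, adjusted p = 0.0478), the single called member of 19 in a lipid metabolism list with 0 called by edgeR when adjusted over the list alone (camera adjusted p = 0.0483, adjusted p = 0.855 with an estimated correlation). With the library number range as a covariate its log2 was 0.65, and the fatty acid and lipid metabolism list was higher (adjusted p = 5.54e-07). The list was not called without WT_vehicle 2 (adjusted p = 0.455) or WT_VitD 1 (adjusted p = 0.0794). The Fasn call ended without any single vehicle library or WT_VitD library (adjusted p from 0.0701 to 0.236).

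The libraries also differed technically. Ribosomal protein genes took 4.58% to 5.23% of counts in the 3 libraries of the higher number range and at most 2.45% in the 5 others, Tet2KO_VitD 2 at 2.41% included. Ribosomal RNA-like symbols took 1.96% of counts in WT_VitD 1, 0.339% in WT_VitD 2 and at most 0.086% elsewhere, with 0.0418% in Tet2KO_VitD 1. The mitochondrial ribosomal RNA gene mt-Rnr2 had 99 counts in Tet2KO_VitD 1 and 8664 to 22346 in every other library. Libraries of the higher number range thus differed among themselves in ribosomal RNA. The rank correlation across genes between transcript length and the deviation of a library was -0.475 and -0.36 in the WT_VitD libraries and -0.115 in Tet2KO_VitD 1, against 0.223 in Tet2KO_VitD 2, 0.355 in WT_vehicle 1, -0.018 in WT_vehicle 2, and 0.305 and 0.409 in the Tet2KO_vehicle libraries. The same correlation with GC content was 0.429 in WT_vehicle 2 and between -0.231 and 0.185 in the others, and WT_vehicle 2 lay at -40.4 on the next principal component, where the others lay between -16.1 and 34.3. On the leading principal component the vehicle libraries lay between -58 and -41, the WT_VitD libraries at 58.9 and 81.7, Tet2KO_VitD 1 at 62.4 and Tet2KO_VitD 2 at -5.77. Number range and treatment overlap almost entirely, and Tet2KO_VitD 2 is the single VitD library in the lower range. In WT the overlap is complete, with both vehicle libraries in the lower range and both VitD libraries in the higher. WT libraries alone thus cannot part a VitD effect from the range, for single genes or for lists. WT values with the range as a covariate rest on the difference between Tet2KO_VitD 1 and Tet2KO_VitD 2. With that covariate, VitD against vehicle in the libraries labelled Tet2 knockout rests on Tet2KO_VitD 2 alone. Genotype under VitD and the interaction then rest on Tet2KO_VitD 1 alone. For these contrasts the covariate nearly repeats the fit without the other Tet2KO_VitD library and is not a separate check.

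**Figure D2:**
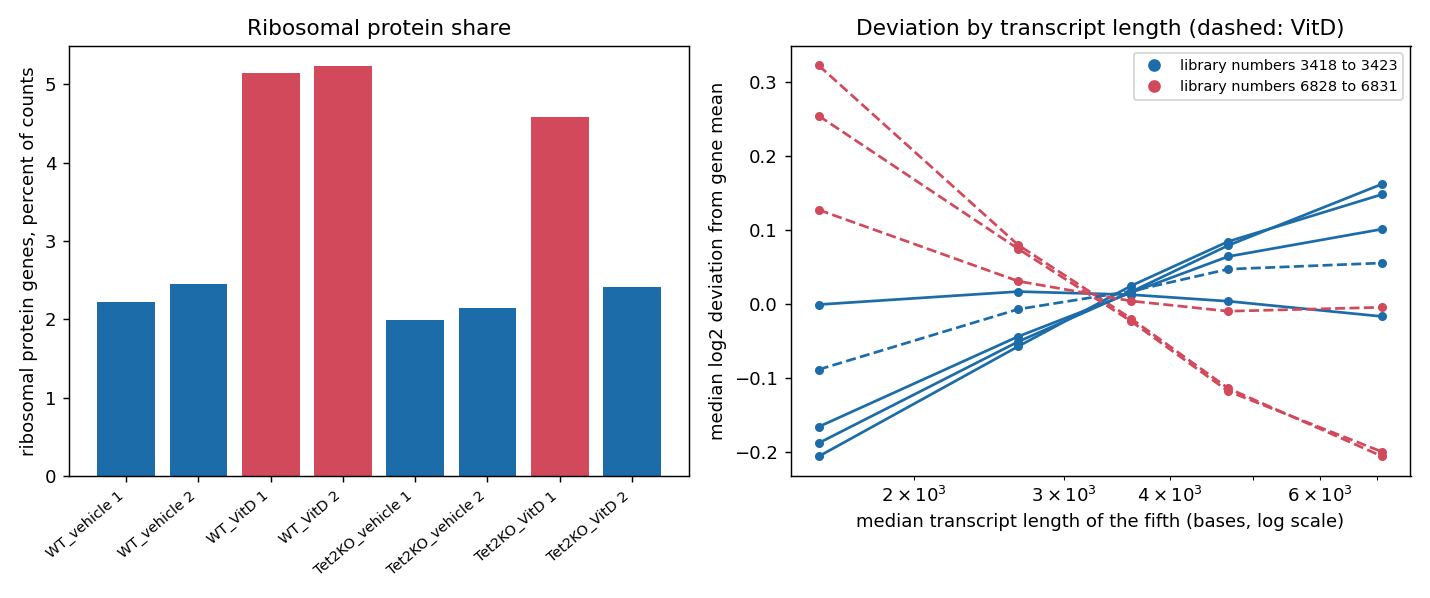
Left, percent of counts in ribosomal protein genes per library, with bars from 0. Right, median log2 deviation from the gene mean in bins of transcript length (log axis), with VitD libraries dashed. The 3 libraries of the higher number range have a share of 4.58% or more, and the others 2.45% or less.

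VitD against vehicle in the libraries labelled Tet2 knockout asks whether the response is kept. Spp1 rose from 4.91 ± 0.865 to 378 ± 287 CPM (log2 6.26, SE 0.575, adjusted p = 0.00505). Prg4, a lubricating proteoglycan, rose 21.5-fold (log2 4.43, SE 0.364, adjusted p = 0.00405) and Ptgs2, the inducible cyclooxygenase, 6.03-fold (log2 2.59, SE 0.225, adjusted p = 0.00405). The adipokine C1qtnf3 (7.99-fold lower, SE of the log2 0.314, adjusted p = 0.0102), the phospholipase Pla2g2d (log2 -2.97, SE 0.387) and the Wnt inhibitor Wif1 (log2 -1.87, SE 0.268) fell. Myh11 had a log2 of -0.60 (SE 0.426, adjusted p = 0.541), Acta2 -0.29 (SE 0.31), Runx2 0.25 (SE 0.414) and Tet2 -0.26 (SE 0.209). Runx2 was -0.019 without Tet2KO_VitD 2. In all, 32 genes changed, 29 higher and 3 lower. Other large rises were Hmga2 (6.48), the serpin Serpina3m (6.08), Chil3 (5.18), the B cell chemokine Cxcl13 (4.85), the cytochrome Cyp2b10 (4.66) and the receptor Cd300lf (4.29), all as log2.

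Among modulated smooth muscle genes 3 of 16 were called higher in the libraries labelled Tet2 knockout, 12 adjusted over the list alone (camera adjusted p = 1.6e-23, adjusted p = 0.177 with an estimated correlation), with Timp1 up 10.6-fold and the protease Mmp3 up 4.05-fold. Inflammation had 3 of 20 called, 15 adjusted over the list alone (adjusted p = 1.2e-23, adjusted p = 0.158 with an estimated correlation). Besides Ptgs2, Lcn2 rose 18.1-fold and the monocyte chemokine Ccl2 8.06-fold. Macrophages had 2 of 15 called, 13 adjusted over the list alone (adjusted p = 1.57e-20, adjusted p = 0.177 with an estimated correlation), namely Trem2, up 5.83-fold, and Ctss, up 4.04-fold. No contractile gene was called, 0 of 20 by edgeR and 0 adjusted over the list alone, while the list fell by camera (adjusted p = 0.0482, adjusted p = 0.76 with an estimated correlation), with Synpo2 at -0.93 (SE 0.341) and Itga8 at -0.86 (SE 0.332). The contractile smooth muscle list was not called without WT_vehicle 1 (adjusted p = 0.0603), WT_vehicle 2 (0.0624), Tet2KO_vehicle 1 (0.0771) or Tet2KO_VitD 1 (0.633), or with the number range as a covariate (0.637). Vitamin D response had 0 of 7 called, 4 adjusted over the list alone (adjusted p = 0.000298, adjusted p = 0.177 with an estimated correlation), with Vdr at 2.10 (SE 0.397, adjusted p = 0.0886) and Fgf23 at least 11.8-fold higher (adjusted p = 0.102). Calcification inhibitors had 0 of 9 called and 4 adjusted over the list alone (adjusted p = 0.00801, adjusted p = 0.178 with an estimated correlation), with Gas6 at 1.26 and Ahsg at 2.29. The calcification inhibitors list was not called without WT_vehicle 1 (adjusted p = 0.063), WT_vehicle 2 (0.0636), Tet2KO_vehicle 2 (0.146) or Tet2KO_VitD 1 (0.0559). Interferon response had 0 of 16 and 12 (adjusted p = 1.5e-11, adjusted p = 0.177 with an estimated correlation), with Irf7 at 1.54 and Bst2 at 0.82, and oxidative stress 0 of 14 and 7 (adjusted p = 3.41e-08, adjusted p = 0.249 with an estimated correlation), with Mt1 7.98-fold higher (adjusted p = 0.0524) and Gpx3 at 1.20. The osteochondrogenic list was called higher in the libraries labelled Tet2 knockout (adjusted p = 0.0019, adjusted p = 0.249 with an estimated correlation), with 11 of 17 values above 0, Spp1 as the single gene called and 3 adjusted over the list alone, but not without Tet2KO_vehicle 2 (adjusted p = 0.0714).

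Lists of other cells and tissue were also called in these libraries. The list of T cells and thymocytes was lower, with 11 of 12 values below 0 and a median log2 of -1.68 (camera adjusted p = 0.000235, adjusted p = 0.511 with an estimated correlation), but not called without Tet2KO_VitD 2 (adjusted p = 0.111). The white adipocytes list was lower with a median of -0.602 (adjusted p = 0.00877, adjusted p = 0.653 with an estimated correlation), and the fatty acid and lipid metabolism list with 19 of 19 values below 0 (adjusted p = 4.87e-06, adjusted p = 0.547 with an estimated correlation). Neither was called without Tet2KO_VitD 1 (adjusted p = 0.849 and 0.242) or with the number range as a covariate (0.852 and 0.259). Neutrophil genes were higher, with 8 of 11 values above 0 (adjusted p = 1.55e-05, adjusted p = 0.343 with an estimated correlation).

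The 32 calls in the libraries labelled Tet2 knockout depend on the tool or filter and on single libraries. DESeq2, run without the filter of the main fit, called 461, and limma voom with it 8. Without a filter edgeR called 1225, and with it 2 when only the groups compared were fitted. The count was 1898 without Tet2KO_VitD 2, 8 without WT_vehicle 1, 8 without WT_vehicle 2, 1 without Tet2KO_vehicle 1 and 0 by edgeR without Tet2KO_vehicle 2, where 1314 genes had an unadjusted p under 0.05 against 2148 with all libraries. Of the 18 called genes named for this comparison, 0 kept their call in edgeR without Tet2KO_vehicle 1 or 2, Spp1 included (adjusted p = 0.0906 and 0.149), 5 without WT_vehicle 1 or 2, 15 without WT_VitD 1 or 2, 12 without Tet2KO_VitD 1 and 18 without Tet2KO_VitD 2.

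Across the 16194 genes the VitD effects in WT and in the libraries labelled Tet2 knockout, which share no library, had a Pearson correlation of 0.63 and a Spearman correlation of 0.708, and 80% had the same sign. The Pearson correlation was 0.364 without Tet2KO_VitD 1 and 0.481 to 0.629 when another library was left out. Genes are not independent replicates, so no p-value is given. Of the calls, 29 were higher in both, against 3.08 for independent lists of these sizes, and 3 were lower in both, against 0.284. Both contrasts take their estimate of spread from the same fit, and Tet2KO_VitD 1 shares the higher number range with the WT_VitD libraries. With all libraries, the overlap and the correlation therefore do not part a shared VitD response from a shared effect of the range. The correlation of 0.364 without Tet2KO_VitD 1 takes its knockout side from libraries of the lower range only. A difference in range does not enter that side, which rests on a single VitD library. The 1718 genes higher in WT had a median log2 of 0.952 in Tet2KO_VitD 1 and 0.437 in Tet2KO_VitD 2, relative to vehicle of the same label. The 1533 lower genes had medians of -0.862 and -0.231. Of the higher genes, 96.9% lay above vehicle in Tet2KO_VitD 1 and 92.5% in Tet2KO_VitD 2. Of the lower genes, 97.8% and 85.5% lay below it. The genes were chosen by their calls in WT, which inflates their WT medians (1.44 and -1.25), so the latter do not measure a difference between genotype labels.

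**Figure D3:**
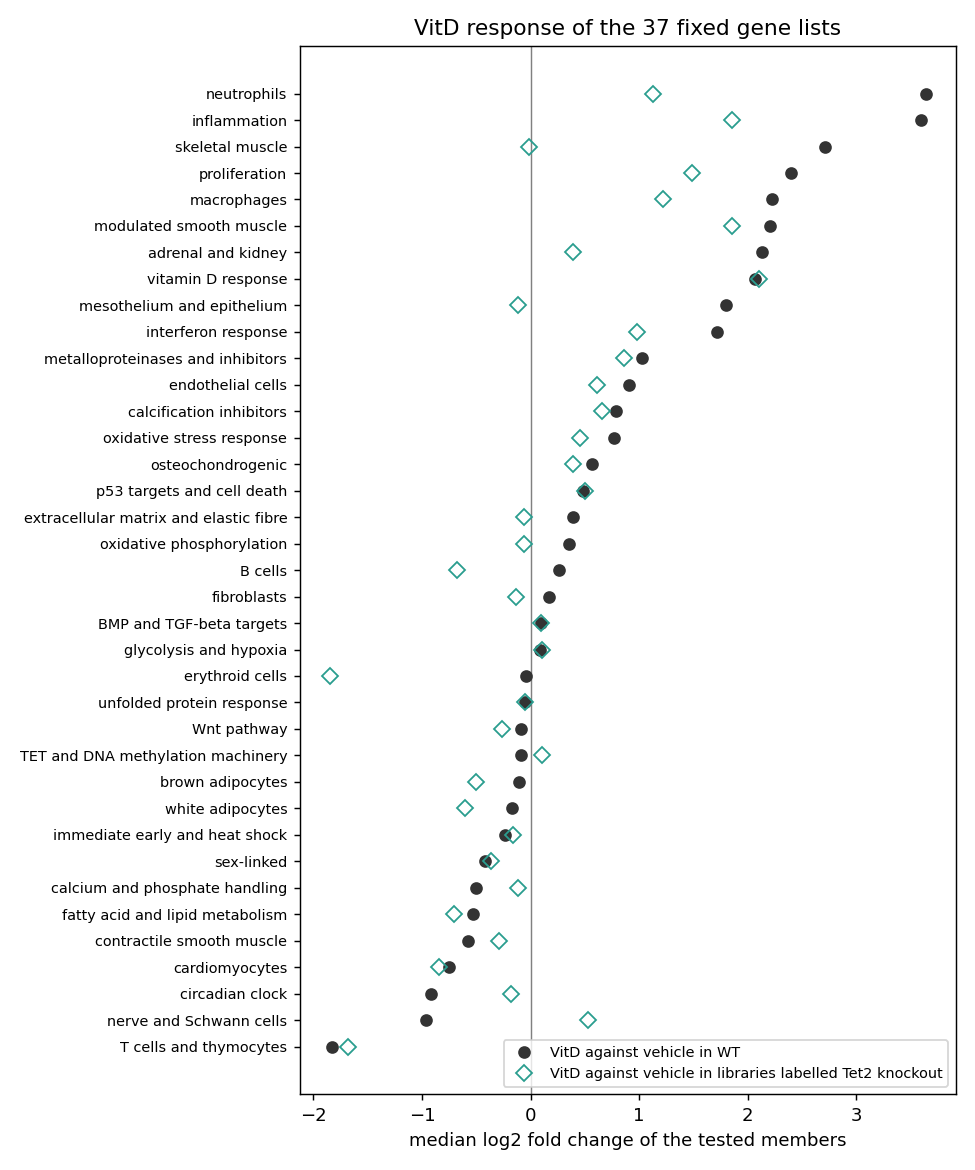
Median log2 fold change of VitD against vehicle over the tested members of 37 gene lists, in WT (filled circles) and in libraries labelled Tet2 knockout (open diamonds). Inflammation lies at 3.60 in WT and 1.86 in the libraries labelled Tet2 knockout, and vitamin D response at 2.07 and 2.10.

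The libraries labelled Tet2 knockout against WT under vehicle ask what the genotype does without treatment. The chemokine gene Ccl8 had a log2 fold change of 2.83 (SE 0.446, adjusted p = 0.562) and Ptgs2 0.95 (SE 0.222, adjusted p = 1). The macrophage genes Itgam and Mrc1 had 1.02 (SE 0.275) and 0.83 (SE 0.229). Spp1 stood at 1.78 (SE 0.568, adjusted p = 1), Runx2 at 0.22 (SE 0.421), Acta2 at 0.03 (SE 0.31) and Myh11 at -0.01 (SE 0.425). Without WT_vehicle 2 Runx2 was -0.21, Acta2 -0.016 and Myh11 0.047, and Myh11 was 0.12 without Tet2KO_vehicle 2, 0.0023 without WT_VitD 1 and 0.0032 without a low-count filter. Inflammation was higher as a list (camera adjusted p = 3.4e-16, adjusted p = 0.332 with an estimated correlation), with 3 genes called when adjusted over the list alone, and so were macrophage genes (adjusted p = 3.74e-09, adjusted p = 0.674 with an estimated correlation), with 2 adjusted over the list alone. Nerve and Schwann cell genes were lower (adjusted p = 0.000227, adjusted p = 0.674 with an estimated correlation), with the catecholamine enzymes Th at -4.04 (SE 1.38) and Dbh at -3.67 (SE 1.45), and the nerve and Schwann cells list was not called without WT_vehicle 2 (adjusted p = 0.469). The skeletal muscle list was lower, with 11 of 11 values below 0 and a median log2 of -0.955 (adjusted p = 1.37e-06, adjusted p = 0.674 with an estimated correlation). The mesothelium and epithelium list was higher, with 8 of 9 values above 0 and a median of 0.85 (adjusted p = 0.0139, adjusted p = 0.696 with an estimated correlation), but not without WT_vehicle 1 (adjusted p = 0.0636), WT_vehicle 2 (0.146) or Tet2KO_vehicle 2 (0.435, in the lower direction). The neutrophils list was higher with 10 of 11 values above 0 (adjusted p = 0.012, adjusted p = 0.696 with an estimated correlation), but not without WT_vehicle 2 (adjusted p = 0.597) or Tet2KO_vehicle 1 (0.784, in the lower direction). The fatty acid and lipid metabolism list was higher with a median of 0.213 (adjusted p = 0.0132, adjusted p = 0.833 with an estimated correlation), but not without WT_vehicle 1 (0.868, in the lower direction) or Tet2KO_vehicle 2 (0.229). Contractile genes were not called as a list (adjusted p = 0.482), with Pcp4l1 at -0.36 and Myl9 at -0.25. No single gene passed in edgeR (0 genes, 481 at an unadjusted p under 0.05 against 810 by chance), and the smallest adjusted p was 0.149. DESeq2 called 19 and limma voom 0, with 455 and 482 genes at an unadjusted p under 0.05.

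The libraries labelled Tet2 knockout against WT under VitD ask whether genotype alters the treated aorta. The contractile smooth muscle list was higher (camera adjusted p = 0.00403, adjusted p = 0.685 with an estimated correlation), with 16 of 20 values above 0, Myh11 at 1.24 (SE 0.431), Synpo2 at 1.09 (SE 0.342) and Mylk, the myosin light chain kinase, at 0.91 (SE 0.308). The modulated smooth muscle list was lower (adjusted p = 4.36e-05, adjusted p = 0.533 with an estimated correlation), with 3 called when adjusted over the list alone and Timp1 at -1.22 (SE 0.321). Inflammation was lower too (adjusted p = 0.000104, adjusted p = 0.533 with an estimated correlation), with Cxcl5 at -2.08 (SE 0.617) and Ccl5 at -1.42 (SE 0.496). The neutrophils list had 11 of 11 values below 0 and a median of -1.09 (adjusted p = 4.25e-05, adjusted p = 0.533 with an estimated correlation), macrophages a median of -0.337 (adjusted p = 0.00752, adjusted p = 0.685 with an estimated correlation) and erythroid cells 6 of 6 values below 0 with a median of -1.49 (adjusted p = 0.000866, adjusted p = 0.569 with an estimated correlation). The macrophages and erythroid cells lists were not called without Tet2KO_VitD 2 (adjusted p = 0.674 and 0.292), without WT_VitD 2 (0.23 and 0.106) or with the number range as a covariate (0.681 and 0.171). B cells (adjusted p = 0.439) and T cells and thymocytes (adjusted p = 0.348) were not called. The calcification inhibitors list was called lower (adjusted p = 0.0402, adjusted p = 0.533 with an estimated correlation), but 4 of its 9 values lay above 0 and 5 below, around a median of -0.102. In edgeR 0 of the 9 genes were called and 1 adjusted over the list alone, with Tnfrsf11b at -0.93 (SE 0.21) and Smad6 at -0.46 (SE 0.191). Skeletal muscle genes were lower with 10 of 11 adjusted over the list alone (adjusted p = 7.13e-24, adjusted p = 0.533 with an estimated correlation), with Acta1 at -3.28 (SE 0.47) and Mylpf at -3.91 (SE 0.598). The mesothelium and epithelium list was lower in 9 of 9 values (adjusted p = 6.15e-05, adjusted p = 0.533 with an estimated correlation), but not called without WT_VitD 2 (adjusted p = 0.0551). Tet2KO_VitD 2 stood apart from the other VitD libraries on the leading principal component (-5.77 against 58.9 or more). Without it the contractile smooth muscle list had an adjusted p of 0.393, modulated smooth muscle 0.119 and calcification inhibitors 0.781, while inflammation stayed at 0.0272. The number range as a covariate gave 0.399, 0.124, 0.818 and 0.0246. This is not a separate check, since that fit too sets Tet2KO_VitD 1 alone against the WT_VitD libraries. Without WT_VitD 2 contractile smooth muscle had 0.395 and inflammation 0.0716, and without WT_VitD 1 calcification inhibitors had 0.0513. Spp1 had -0.82 (SE 0.451), Acta2 0.32 (SE 0.31) and Runx2 -0.19 (SE 0.411). Acta2 was -0.014 without Tet2KO_VitD 2 and -0.012 with the number range as a covariate, and Runx2 was 0.045 without WT_VitD 2 and 0.012 without Tet2KO_VitD 1. Fasn and Acaca, lipid synthesis enzymes, had 3.54 (SE 1.24) and 2.05 (SE 0.84). In that lipid metabolism list, which was not called (adjusted p = 0.636), both turn negative without Tet2KO_VitD 2, to -0.40 and -0.064. The fatty acid and lipid metabolism list was called lower without Tet2KO_VitD 2 (adjusted p = 3.68e-10) and with the number range as a covariate (4.71e-10), and higher without Tet2KO_VitD 1 (4.18e-06).

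Under VitD no single gene passed between genotypes in edgeR (0 genes, 1719 at an unadjusted p under 0.05), with a smallest adjusted p of 0.16. DESeq2 called 92, limma voom 0, and the fit with the number range as a covariate 16. The count was 674 without Tet2KO_VitD 1, 16 without Tet2KO_VitD 2, 8 without WT_VitD 1 and 3 without WT_VitD 2, and the number of lists called was 10 without WT_VitD 2 against 17.

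The interaction asks whether the VitD response differs by genotype label. Spp1 had an interaction log2 of -2.60 (SE 0.726, adjusted p = 0.794) and Myh11 1.24 (SE 0.603, adjusted p = 0.801), neither of which passed the test. Ccl8 stood at -3.76 (SE 0.582, adjusted p = 0.655) and the cytokine Il1b at -2.82 (SE 0.699, adjusted p = 0.794), and the inflammation list was lower (camera adjusted p = 3.86e-16, adjusted p = 0.322 with an estimated correlation), with 2 genes called when adjusted over the list alone. The contractile smooth muscle list had 19 of 20 values above 0 (adjusted p = 0.00403, adjusted p = 0.573 with an estimated correlation), with Mylk at 0.98 (SE 0.434) and Acta2 at 0.29 (SE 0.438). It was not called without Tet2KO_VitD 2 (adjusted p = 0.175), without WT_VitD 2 (0.216) or with the number range as a covariate (0.177), and Acta2 was -0.048 without Tet2KO_VitD 2 and -0.043 with that covariate. The osteochondrogenic list was not called (adjusted p = 0.708), with Phex at 1.16 (SE 0.667) and Runx2 at -0.41 (SE 0.588, but 0.014 without WT_vehicle 2). Tet2, which is not in that list, stood at 0.56 (SE 0.298). No single gene differed in edgeR (0 genes, 1006 at an unadjusted p under 0.05, smallest adjusted p 0.575), while DESeq2 called 18 and limma voom 0. Without Tet2KO_VitD 1 the edgeR count was 37 and without Tet2KO_VitD 2 it was 13.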

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

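All tests of explanations in this part were chosen after the result was seen, while the list tests were planned. Camera's test of the interaction, which ranks the genes of a list against other genes, called 21 of 37 lists. With an estimated correlation 0 lists were called (2 at an unadjusted p under 0.05, and fry called 0). Both WT_VitD libraries but only 1 Tet2KO_VitD library lie in the higher number range. An effect of the range therefore enters this contrast and can look like a weaker response in the libraries labelled Tet2 knockout. With the range as a covariate 19 lists were called by camera, contractile smooth muscle not among them. The values that follow are median log2 differences of the response, libraries labelled Tet2 knockout minus WT. Lists of the vessel wall stood at 0.289 for contractile smooth muscle, 0.437 for calcium and phosphate handling, -0.812 for modulated smooth muscle, -0.359 for extracellular matrix and elastic fibre and -0.636 for metalloproteinases and inhibitors. Stress and growth lists stood at -1.75 for inflammation, -0.886 for interferon response, -0.911 for proliferation, -0.313 for oxidative phosphorylation and 0.696 for the circadian clock. Cell type lists stood at -0.29 for endothelial cells, -0.34 for fibroblasts, -0.481 for brown adipocytes, -0.868 for macrophages, -1.60 for neutrophils, -1.22 for B cells, -2.44 for skeletal muscle, 1.30 for nerve and Schwann cells, -1.62 for erythroid cells, -1.97 for mesothelium and epithelium and -1.5 for adrenal and kidney. Without Tet2KO_VitD 2 the lists of contractile smooth muscle (adjusted p = 0.175), calcium and phosphate handling (0.0665), metalloproteinases and inhibitors (0.0933), fibroblasts (0.0665), erythroid cells (0.0665) and adrenal and kidney (0.175) were not called. Without Tet2KO_VitD 1 metalloproteinases and inhibitors (0.0544), oxidative phosphorylation (0.157), brown adipocytes (0.732), B cells (0.0889) and adrenal and kidney (0.265) were not called. The same held without WT_VitD 1 for oxidative phosphorylation (0.0758), endothelial cells (0.106), fibroblasts (0.116), brown adipocytes (0.0758) and adrenal and kidney (0.0758), and without WT_VitD 2 for contractile smooth muscle (0.216), metalloproteinases and inhibitors (0.295), B cells (0.119) and adrenal and kidney (0.161). Without WT_vehicle 1 it held for calcium and phosphate handling (0.0711), oxidative phosphorylation (0.591), endothelial cells (0.155), brown adipocytes (0.296) and adrenal and kidney (0.146), and without WT_vehicle 2 for fibroblasts (0.147), erythroid cells (0.0615) and adrenal and kidney (0.113). Without Tet2KO_vehicle 2 it held for endothelial cells (0.0904), fibroblasts (0.215), brown adipocytes (0.187), B cells (0.353) and adrenal and kidney (0.473).

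Tet2KO_VitD 2, the single VitD library numbered in the lower range, lay between the vehicle libraries and the other VitD libraries. The number range alone is argued against, since 22 genes were called between it and the vehicle libraries of the same label, all of that range, when Tet2KO_VitD 1 was left out. A part set by the range may be present, since its ribosomal protein share of 2.41% lay under the highest vehicle share of 2.45%. A weaker response of that sample stays open and was not tested.

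Contractile genes moved unevenly in WT, with 5 of 20 called lower and a median log2 of -0.572 over all 20, and the difference of the list's median per library was -0.613 (SE 0.235, 95% interval -1.26 to 0.0383 in a linear model over the 8 libraries), so over the whole list a fall is not beyond the spread between libraries. A length bias as the whole source is argued against, since that difference was -0.712 (SE 0.22, interval -1.32 to -0.101) with the length trend removed, and 4 of the 20 were called. A lower share of smooth muscle stays open. Medians of endothelial, fibroblast, white adipocyte and nerve lists spread over 1.87 against a member SD of 1.07, beyond the SD in 20 of 20 fits. Without the endothelial list they spread over 1.13 against 1.2, beyond it in 4 of 20. The endothelial median turned from 0.905 to the lowest of these lists with the number range as a covariate. This spread cannot decide, since a lower share of smooth muscle need not raise these lists alike. Lists left out of it went both ways in WT, with medians of 2.22 for macrophages and 3.64 for neutrophils but -1.83 for T cells and thymocytes. The library number range cannot be told apart from a VitD effect on these genes, since with it as a covariate the difference was -0.201 (SE 0.368, interval -1.37 to 0.97) and 0 contractile genes were called by edgeR, in a fit where Tet2KO_VitD 2 alone parts range from treatment.

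Fasn was low in WT under VitD, at a log2 of -4.24. A loss of adipose tissue as large as the fall of Fasn is argued against, since the white adipocyte list had a median of -0.171 (SD 1, lowest -2.48). A smaller loss stays open, since Fasn was picked for its large fall, which made a gap to that list likely beforehand. The median is also from the fit without the range as a covariate. The library number range could account for it, since with that covariate the log2 was 0.65 (SE 0.942), and Fasn stood at 112 to 155 CPM in the 3 libraries of the higher range and 1070 CPM or more in the others. A weaker VitD effect in Tet2KO_VitD 2 would give the same values and stays open.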

How the results depend on the processing

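Removal of length or GC trends and fry were chosen after seeing the data, the other alternatives before. Where a value moved, the cause was not tested, except that leaving out a library leaves fewer samples, and its lone partner is then assumed to vary like the other groups. Genes changed by VitD in WT (3251) numbered 58 with the number range as a covariate and 140 to 4946 when a library was left out. In the libraries labelled Tet2 knockout (32) they numbered 461 by DESeq2, 8 by limma voom, 1225 without a filter, 20 with the range as a covariate, 2 with only the groups compared, 20 with length and 20 with length and GC trends removed, and 0 to 1898 when a library was left out. Counts of 0 in edgeR became 19 by DESeq2 and 164 without a filter for genotype under vehicle (481 at an unadjusted p under 0.05, 0 when any library was left out). For genotype under VitD they became 92, 610 and, with the range, 16 (0 to 674 when a library was left out), and for the interaction 18, 403 and 7 (0 to 37). Lists called by camera numbered 18, 18, 14, 17 and 21 over the 5 contrasts and 0 in each with an estimated correlation. Fry called 12, 7, 0, 0 and 0, and leaving out a library gave 17 to 20, 16 to 23, 10 to 16, 10 to 20 and 16 to 23. The Tet2 difference lay between 0.051 and 0.31 under vehicle and 0.47 and 0.95 under VitD when a library was left out. The correlation of VitD effects (0.63) lay between 0.364 and 0.629 when a library was left out, and was 0.688 with the CPM filter, 0.651 with the replicate block and 0.566 with the range as a covariate. The replicate block gave 2474 genes in WT and 24 in the libraries labelled Tet2 knockout, and same-numbered libraries deviated with correlations of -0.115 to 0.138, so the numbers do not pair the libraries. The share of higher calls in WT was 52.8%, and 96.6% with the range as a covariate, 97.9% without WT_VitD 2, 86.3% without WT_vehicle 1 and 76.3% without WT_VitD 1. Of 136 gene values 14 changed sign under some alternative and 8 outside the left-out libraries. With the range as a covariate Acta2 was 0.018 in WT, -0.012 between genotypes under VitD and -0.043 in the interaction, Ahsg -0.23 and Fasn 0.65 in WT, and Fasn -0.40 and Acaca -0.062 between genotypes under VitD. Without a filter Myh11 was 0.0032 under vehicle. With a library left out, Runx2 lay between -0.019 and 0.48 in the libraries labelled Tet2 knockout, -0.21 and 0.83 between genotypes under vehicle, -0.46 and 0.045 under VitD, and -1.02 and 0.014 in the interaction. In the latter 3 contrasts Acta2 lay between -0.016 and 0.086, -0.014 and 0.60, and -0.048 and 0.56. Myh11 lay between -0.14 and 0.12 under vehicle, Rag1 between -8.56 and 0.64 in WT, and under VitD Fasn between -0.40 and 4.48 and Acaca between -0.064 and 2.86. Cyp24a1 had 0 or 1 counts per library, and whether it is expressed below this depth cannot be read from the counts.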

Other observations

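In this part the test of genes near Tet2 under vehicle was fixed before its result was seen, though after Ank2 had been noticed, and the other tests near Tet2 were chosen after. Genes of p53 targets and cell death rose as a list under VitD in WT, with 4 of 16 called, 8 adjusted over the list alone (camera adjusted p = 0.00917, adjusted p = 0.443 with an estimated correlation). In the libraries labelled Tet2 knockout 0 were called by edgeR and 3 adjusted over the list alone (adjusted p = 0.000874, adjusted p = 0.343 with an estimated correlation). With the library number range as a covariate the list of p53 targets and cell death was not called in WT (adjusted p = 0.555). Endothelial genes had a median log2 of 0.905 in WT, with 2 of 13 called higher and 0 adjusted over the list alone (adjusted p = 0.0221, adjusted p = 0.75 with an estimated correlation), and 0.612 in the libraries labelled Tet2 knockout (adjusted p = 0.126). The endothelial cells list was not called in WT without WT_vehicle 1 (adjusted p = 0.0522) and was lower with the range as a covariate (1.21e-05). In the libraries labelled Tet2 knockout it was lower without Tet2KO_VitD 1 (1.44e-05) and higher without Tet2KO_VitD 2 (1.67e-09). Erythroid genes had a median of -1.85 under VitD in the libraries labelled Tet2 knockout (adjusted p = 0.000103, adjusted p = 0.368 with an estimated correlation) and -0.042 in WT (adjusted p = 0.888), and the erythroid cells list was not called in the former without Tet2KO_VitD 2 (adjusted p = 0.111). B cell genes were higher in the libraries labelled Tet2 knockout under vehicle, with a median of 0.742 (adjusted p = 0.000225, adjusted p = 0.674 with an estimated correlation), though the B cells list was not called without Tet2KO_vehicle 2 (adjusted p = 0.435).

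Some genes were noticed after their values were seen. Gm6166 had 3, 9, 4 and 6 counts in the 4 libraries labelled Tet2 knockout and 57, 87, 81 and 110 in the WT libraries. Slfn8 had 8 and 3 counts in the WT vehicle libraries and 72 or more in the others. Acly, Scd1 and Acaca were, like Fasn, lowest in the 3 libraries of the higher number range, with Acly at 115 to 121 CPM there and 212 CPM or more elsewhere.

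Ank2, on chromosome 3 from 126921612 to 127499350 (mm10) and thus near Tet2, ranked at the top between the genotypes under vehicle, with a log2 of -1.41 (SE 0.167, adjusted p = 0.149). It stood at 97.5 and 115 CPM in the WT_vehicle libraries and at 38.8 to 52.2 CPM in all others. The WT_VitD libraries, at 47.7 and 52.2 CPM, thus lay with those labelled Tet2 knockout. One hypothesis is a flanking stretch that differs between the lines. Under vehicle 18 of 80 genes within 10 Mb of Tet2 (22.5%) had an unadjusted p under 0.05 against 2.90% of other genes (Fisher's exact test, two-sided, p = 1.79e-11, which treats neighbouring genes as independent), and 0 of 15249 windows of that size around other genes were as high (highest 10.9%). Under VitD this was not seen, since 13.8% near Tet2 stood against 10.6% elsewhere (Fisher's exact test, p = 0.36) and 12.8% of windows were as high. Of the 18 genes, 12 lay on the same side under VitD (exact binomial test, two-sided, p = 0.238), where chance is taken as even, and against 38.9% of 453 other such genes Fisher's exact test gave p = 0.0255. Both treat neighbouring genes as independent. Their median log2 along the vehicle direction went from 1.03, which choosing them under vehicle inflates, to 0.185. The 18 genes differed in this, as noticed after their values were seen. Rpl34 stood at -1.27 under vehicle and -1.59 under VitD, Alpk1 at 1.1 and 0.974, and Pla2g12a at -0.643 and -0.664. Dapp1 stood at -0.502 and -0.45. Tram1l1 went from 1.46 to -0.464 and Cfi from 1.49 to -0.463. Ank2 stood at -0.14 (SE 0.165) under VitD, a difference of 1.27 (SE 0.234, adjusted p = 0.794 in edgeR) that choosing the top gene under vehicle inflates. Whether such a stretch acts whatever the treatment therefore stays open, since the answer depends on what is taken as chance.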
